A study of Homo sapiens with 8 samples.

How the data were processed

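Bulk RNA sequencing was carried out on MT-2, an established human T cell line transformed by the virus HTLV-1 and resembling a regulatory T cell. The wild-type line was compared with a line in which CRISPR-Cas9, a guided DNA-cutting enzyme, had been used to delete FOXP3, the transcription factor that defines regulatory T cells. Per the labels' protocols, both lines were seeded at the same density, cultured for 3 days and frozen as pellets, and the experiment was carried out 4 times, which gave 4 libraries per line and 8 libraries in all. A single FOXP3-null line is named in the labels. Groups and replicate numbers were taken from the sample titles.

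Per the submitters' processing notes, reads were converted with bcl2fastq 2.19, STAR and StringTie were used without a stated version, and the genome build was GRCh38. The strandedness of the libraries and the read length were not given in the sources used here. Reads of a gene and of an overlapping gene on the other strand are therefore treated as not separable. 2 tables of the whole series were used, one of counts and one of TPM, the abundance of transcripts relative to all those of the library. The deposited counts are whole numbers, but they are estimated counts: for genes with a single transcript and counts up to 1000, they equalled the deposited TPM multiplied by transcript length, scaled by 1 constant per library and rounded up, in 99.99% to 100% of 6672 to 7648 genes per library, within a tolerance of 0.05 counts. They thus carry the coverage estimate of the upstream tool and were not tallied read by read. Because the values were already whole, they were entered into the count model as deposited. The deposited TPM values were used for an alternative test and for levels of FOXP3. The table held 60666 genes, and 0 rows lacked a name. Gene symbols, identifiers and coordinates are those of the deposited tables.

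The total per library ranged from 55131327 to 81979457 estimated counts. The pairs of libraries within a group differed far beyond counting noise, with chi-square per degree of freedom of 40.8 to 280, so all 8 were treated as separate libraries.

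Differential expression was tested with edgeR 4.0.16 under R 4.3.3, using TMM scaling, the filterByExpr filter, a robust quasi-likelihood fit and a two-sided F test. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. The filter kept 18829 genes, which held 99.9% of the counts. Positive log2 fold changes mean higher expression in the FOXP3-null line. The standard error of a log2 fold change was computed as its size divided by the square root of F. CPM, the counts of a gene relative to the total of its library, were scaled by TMM and are given as mean ± SD. For FOXP3 an exact two-sided permutation test of log2 CPM was added. P-values measure the spread between the 4 cultures of each line, not between independently edited lines.

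30 gene lists were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. They were repeated with an estimated correlation and with fry. The lists covered regulatory T cell genes, genes listed as repressed by FOXP3, T cell identity, cytokines, chemokines, receptors and checkpoints. They also covered signalling and stress responses, metabolism, cell cycle, ribosomal proteins, and markers of 5 other cell types. A gene was counted as detected in one line only when it had at least 10 counts in each of the 4 libraries of one line and at most 1 count in each library of the other. The lists, the main tests, the alternatives listed at the end other than the length and GC correction, and the rule for naming genes were fixed before the data were examined. The length and GC correction and the tests of residual FOXP3 transcripts, of the distal part of chromosome 10 and of gene families were chosen after the results were seen. The rule for naming genes takes FOXP3, its neighbours CCDC22 and PPP1R3F, 6 regulatory T cell and cytokine genes, the 10 protein-coding genes with the highest and the 10 with the lowest log2 fold change, and up to 4 members of each list by adjusted p. The genes with extreme fold changes had to pass the threshold, to have groups that did not overlap and to have a mean of at least 5 CPM in the higher line.

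The fits were tested on simulated counts drawn from the means, dispersions and library sizes of these data, with 200 of 18829 genes changed. The share of changed genes recovered was 0% at 1.5-fold, 45.0% at 2-fold and 74.5% at 4-fold. False calls made up 0%, 7.22% and 6.88% of the calls. In the data 1821 genes were called, and with only 200 changed genes the adjustment of p-values is stricter. These shares can therefore understate recovery in the data, where genes below 2-fold were also called. The median log2 change fitted to the simulated genes was 0.59, 0.97 and 2.02. 1 list with doubled genes was called and 0 of 29 lists without a change were. Genes were drawn independently of each other, so the simulation does not show how the list test behaves when genes are correlated.

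Alternatives were DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), other scalings, other filters, stricter thresholds, a replicate block, each library left out in turn, and a correction for transcript length and GC content (from GENCODE 29 transcripts) chosen after seeing the data. Chromosome medians were compared with 10000 random gene sets of matched expression. Y-linked genes were left out of the genes named by fold change and of the chromosome comparison.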

Results

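Transcript levels were measured by bulk RNA sequencing in the human regulatory T cell-like line MT-2 and in a FOXP3-null line made from it, with 4 cultures of each line grown for 3 days. The wild-type libraries held 67471343, 66940276, 62066137 and 71313163 estimated counts in replicates 1 to 4, and the FOXP3-null libraries held 55131327, 81979457, 69716533 and 78173925. The difference in depth between the lines lay within the spread between libraries (exact two-sided permutation test, p = 0.543). The first principal component of log2 CPM held 40.4% of the variance. Correlations across genes were 0.956 to 0.969 between wild-type libraries, 0.969 to 0.979 between FOXP3-null libraries and 0.930 to 0.960 between the lines. Genes are not independent replicates, so these correlations are descriptive.

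The series asks how transcription differs between MT-2 cells with and without FOXP3, and the targeted gene was examined first. FOXP3 (ENSG00000049768.16, GRCh38 chromosome X, 49250438 to 49270477, minus strand) stood at 165, 189, 160 and 203 CPM in the wild-type libraries. It stood at 3.77, 6.01, 22.3 and 13.7 CPM in the FOXP3-null libraries, which is 2.11%, 3.36%, 12.5% and 7.68% of the wild-type mean. FOXP3 mRNA was thus 15.6-fold lower in the FOXP3-null line, with a log2 fold change of -3.96 ± 0.48 (SE) and an adjusted p of 0.000833 in the edgeR quasi-likelihood test. The exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 libraries allow. In the deposited TPM the means were 143 ± 14.7 (SD, n = 4) and 9.98 ± 7.15 (SD, n = 4). The levels of the 4 FOXP3-null libraries spanned a 5.92-fold range. Counting error alone was small: the FOXP3-null library with the fewest counts had 201, with a 95% Poisson interval of 3.27 to 4.33 CPM, which covers counting error only.

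Both genes next to FOXP3 overlap its ends on the other strand. CCDC22, which shares 83 bases with FOXP3, had a log2 fold change of 0.25 ± 0.13 (SE, adjusted p = 0.266). PPP1R3F fell by 1.04 on the log2 scale (SE 0.23, adjusted p = 0.0170), but it shares 685 bases with the 5' end of FOXP3, so reads of FOXP3 could not be told from its own. The PPP1R3F call was lost without wild-type replicate 3 (adjusted p = 0.0509), FOXP3-null replicate 1 (adjusted p = 0.0608) or FOXP3-null replicate 2 (adjusted p = 0.0507).

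**Figure D1:**
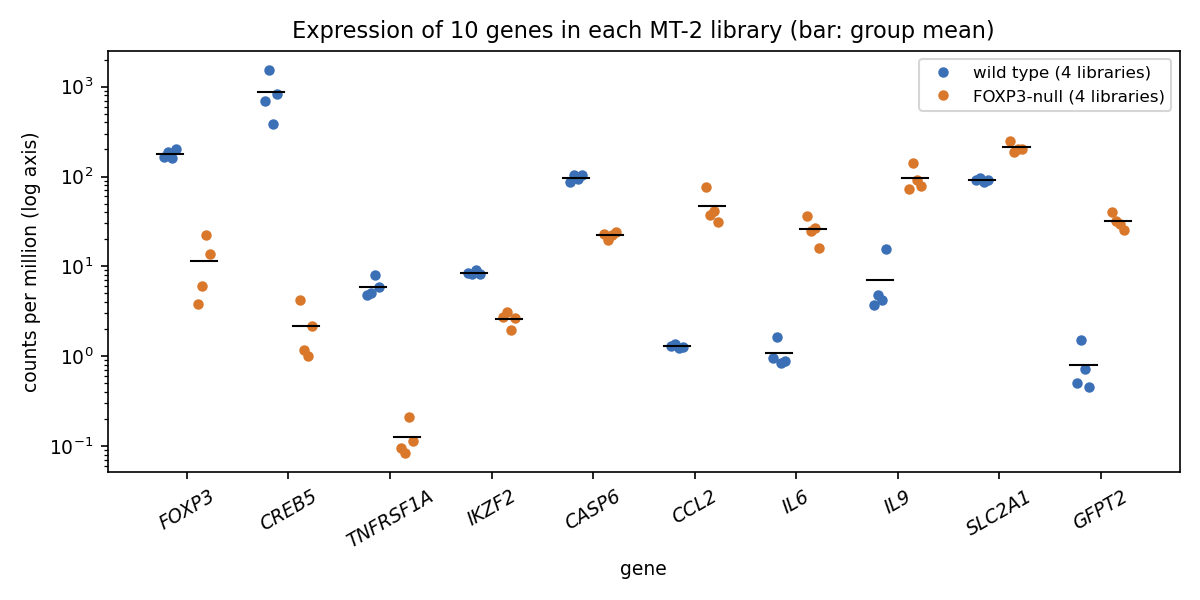
CPM (log axis) of 10 genes in each library, with 4 wild-type libraries in blue, 4 FOXP3-null libraries in orange and a bar at each group mean. FOXP3, CREB5, TNFRSF1A, IKZF2 and CASP6 lay lower in every FOXP3-null library than in any wild-type library, and CCL2, IL6, IL9, SLC2A1 and GFPT2 lay higher.

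Among the genes named by fold change, the lowest log2 fold change was that of CREB5, a transcription factor of the CREB family, which fell from 863 ± 488 CPM (SD, n = 4) to 2.14 ± 1.48 CPM (SD, n = 4), a log2 fold change of -8.67 ± 0.65 (SE, adjusted p = 5.04e-05). CREB5 (ENSG00000146592.17) lies on chromosome 7 from 28299321 to 28825894. TNFRSF1A, the receptor through which most cells respond to TNF, fell 46.8-fold from 5.94 ± 1.42 to 0.125 ± 0.0576 CPM (SD, n = 4 each). Other strongly lower genes were HCLS1, a signalling adaptor of blood cells (66.1-fold lower), the growth factor gene FGF1 (63.6-fold lower), PDILT (66.5-fold lower) and NLRP2, whose log2 fold change of -6.33 became -8.26 without FOXP3-null replicate 4, the library with 19 counts against at most 4 in the other FOXP3-null libraries. CT45A3, CT45A5, CT45A6 and CT45A7 were 53.6-fold to 61.3-fold lower, but they are near-identical copies and their separate counts are uncertain. Wild-type replicate 4 held 15.9 to 18.9 CPM of each against at most 5.00 CPM in the other wild-type libraries, and without it their log2 fold changes of -5.94 to -5.74 became -4.73 to -4.57, still past the threshold; limma-voom did not call CT45A3 (adjusted p = 0.0558). In the other direction, GFPT2, an enzyme of the hexosamine pathway, rose 40.0-fold from 0.793 ± 0.484 to 31.8 ± 6.10 CPM, and CCL2, which attracts monocytes, rose 36.0-fold from 1.29 ± 0.0607 to 46.6 ± 20.4 CPM (SD, n = 4 each). The cytokine gene IL6 rose 24.3-fold, the neuropeptide gene NPW 20.7-fold, the muscarinic receptor gene CHRM3 19.3-fold, the chemokine gene CCL1 16.5-fold and the carbonic anhydrase gene CA2 14.6-fold. ANXA8 and ANXA8L1 were 26.3-fold and 24.2-fold higher, but they too are near-identical copies. SERTAD4 rose 42.9-fold (log2 fold change 5.42, and 7.21 without wild-type replicate 1), and reads from its antisense gene could not be told from its own. Each of these genes passed the threshold (adjusted p from 2.06e-06 to 0.00468), with no overlap between the groups.

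Across the transcriptome, 1821 of 18829 genes passed the threshold of the edgeR quasi-likelihood test, 889 of them higher and 932 lower in the FOXP3-null line. Of these, 1016 had a fold change above 2-fold, 501 higher and 515 lower. Protein-coding genes made up 1614 of the calls (of 13576 tested) and long non-coding RNA genes 121 (of 2688 tested). The groups did not overlap for 3348 genes, 17.8% of those tested, where chance gives 2.86%. The number of calls depended on single libraries and fell to 1046, 977 and 1195 without FOXP3-null replicates 1, 2 and 4. DESeq2 called 2948 genes, and limma on log2(TPM + 1) called 1049 higher and 516 lower, on a scale where the median of all genes lay at a log2 fold change of 0.13.

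Regulatory T cell genes were examined as a list of 40, of which 32 could be tested. 6 fell, 0 rose and 26 did not pass the threshold, and adjusted over the list alone 6 fell and 1 rose. IKZF2, which encodes the transcription factor Helios, fell 3.26-fold from 8.49 ± 0.472 to 2.60 ± 0.459 CPM (SD, n = 4 each, adjusted p = 0.000641). The chemokine receptor gene CCR8 fell from 2.82 ± 1.51 to 0.0418 ± 0.0483 CPM (adjusted p = 0.00154; log2 fold change -5.94, and -6.53 without FOXP3-null replicate 2), and ZC3H12D fell 3.10-fold (adjusted p = 0.00664). FANK1 fell 2.41-fold (adjusted p = 0.000971), and it lies in a stretch of chromosome 10 in which nearly all genes were lower, described at the end. Several hallmark genes did not pass the threshold. IL2RA, which encodes the IL-2 receptor alpha chain CD25, stood at 1489 ± 282 CPM in the wild type and 1696 ± 163 CPM in the FOXP3-null line (log2 fold change 0.19 ± 0.16 SE, adjusted p = 0.516). CTLA4 had a log2 fold change of -0.47 ± 0.23 (SE, adjusted p = 0.224) and TNFRSF18, which encodes GITR, one of -0.37 ± 0.25 (SE, adjusted p = 0.389). The list was lower as a set in camera (adjusted p = 0.00454), and this call was lost with an estimated correlation (adjusted p = 0.230).

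Of 15 tested genes listed as repressed by FOXP3, 3 rose and 2 fell, and adjusted over the list alone 3 rose and 3 fell. CCL5 rose 2.63-fold, the cytokine gene CSF2 rose 3.90-fold (named after its value was seen) and ID2, an inhibitor of E proteins, rose 1.87-fold, whereas its relative ID3 fell 3.50-fold and the drug transporter gene ABCB1 fell 1.69-fold, a call lost with limma on log2(TPM + 1), on log2(TPM + 0.1) and on log2(TPM + 1) without a filter (adjusted p = 0.0666, 0.0697 and 0.175). The list did not move as a set (adjusted p = 0.676). IFNG stood at 0.285 ± 0.324 and 0.350 ± 0.534 CPM (SD, n = 4 each, adjusted p = 0.910), with 1.14 CPM in FOXP3-null replicate 3 and at most 0.167 in the other FOXP3-null libraries. Its log2 fold change of 0.31 turned to -1.66 without that library and to -0.14 without wild-type replicate 1. IL2 did not pass the filter on low counts.

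Several inflammatory cytokine and chemokine genes rose. Among chemokines 9 of 16 tested genes rose, 0 fell and 7 did not pass the threshold, with a list median log2 fold change of 1.71, and adjusted over the list alone 10 rose. CCL2 and CCL1 are given above, CCL5 rose from 24.7 ± 3.08 to 64.9 ± 15.6 CPM and CXCL3 rose from 0.666 ± 0.130 to 2.54 ± 0.464 CPM (SD, n = 4 each). CCL1 stood apart in FOXP3-null replicate 1, at 13.2 CPM, and its log2 fold change of 4.04 became 3.67 without that library and 4.70 without wild-type replicate 2. Among T helper cytokines 5 of 19 rose, 0 fell and 14 did not pass, and adjusted over the list alone 6 rose and 2 fell. IL9 rose 13.5-fold from 7.08 ± 5.71 to 95.5 ± 31.4 CPM, with wild-type replicate 4 at 15.6 CPM above the other wild-type libraries; its log2 fold change of 3.75 became 4.50 without that library. IL1A rose 3.84-fold to 92.2 ± 15.8 CPM and TNF 2.72-fold to 30.1 ± 9.40 CPM (SD, n = 4 each). The chemokine list (adjusted p = 2.58e-11) and the cytokine list (adjusted p = 0.000277) passed camera, and neither call held with an estimated correlation (adjusted p = 0.230 and adjusted p = 0.326). Targets and components of NF-kB, a transcription factor of inflammation, were higher as a list (adjusted p = 0.00226; adjusted p = 0.521 with an estimated correlation). 4 of its 34 members rose, 3 of which encode chemokines, and the fourth was TNFAIP2 (2.54-fold). CYLD, which encodes an inhibitor of the pathway, was its 1 member to fall (1.52-fold), a call lost without wild-type replicate 2 or 3 or FOXP3-null replicate 1, 2 or 3 (adjusted p from 0.0570 to 0.111), and adjusted over the list alone the counts were likewise 4 and 1.

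Several genes of amino acid synthesis and the amino acid stress response fell. In the list of the unfolded protein and amino acid stress response, 10 of 28 genes fell, 0 rose and 18 did not pass, and adjusted over the list alone 11 fell and 1 rose. PHGDH and PSAT1, enzymes of serine synthesis, fell 2.23-fold (from 375 ± 65.5 to 168 ± 6.22 CPM) and 2.42-fold (from 305 ± 87.2 to 126 ± 10.3 CPM). Asparagine synthetase, ASNS, fell 2.29-fold and the stress-induced gene DDIT4 fell 4.13-fold (SD, n = 4 each). The list passed camera (adjusted p = 9.60e-05), and the call was lost with an estimated correlation (adjusted p = 0.230).

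Most ribosomal protein mRNAs fell by less than 2-fold. 27 of 40 fell, 0 rose and 13 did not pass, with a median log2 fold change of -0.62 and an interquartile range of -0.68 to -0.51, and adjusted over the list alone 39 fell. RPL11 fell 1.83-fold from 1077 ± 195 to 590 ± 9.23 CPM, RPLP1 fell 1.72-fold and RPL3 fell 1.56-fold (SD, n = 4 each). The list had the smallest p of the 30 in camera (adjusted p = 7.61e-19), and this call too was lost with an estimated correlation (adjusted p = 0.367). The 13 mRNAs encoded by the mitochondrial genome were higher as a list, with a median log2 fold change of 0.44. In the edgeR test 0 of them passed, also 0 adjusted over the list alone, 4 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. The list passed camera (adjusted p = 0.0156; adjusted p = 0.759 with an estimated correlation). The mitochondrial share of counts was 3.09 ± 0.359% in the wild type and 4.03 ± 0.741% in the FOXP3-null line (SD, n = 4 each), a difference that did not pass the threshold (exact two-sided permutation test, p = 0.0857). This list's call was lost without wild-type replicate 3 (adjusted p = 0.0619) or FOXP3-null replicate 1 (adjusted p = 0.177).

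Of 27 tested p53 target genes 8 rose, 1 fell and 18 did not pass, and adjusted over the list alone 11 rose and 3 fell. TP53I3 rose 4.21-fold, PLK2 4.44-fold, PHLDA3 1.97-fold and SESN1 1.97-fold (camera adjusted p = 0.000275; adjusted p = 0.402 with an estimated correlation). In the type I interferon response, 3 of 31 genes rose and 5 fell, with 4 and 7 adjusted over the list alone. The antiviral genes MX1 (2.27-fold) and MX2 (3.64-fold) rose, MX1 overlapping a gene of the other strand that also rose, whereas USP18 (1.91-fold) and SAMD9 (2.01-fold) fell. The interferon list was lower as a set (adjusted p = 0.00749; adjusted p = 0.599 with an estimated correlation), a call lost without wild-type replicate 2 (adjusted p = 0.0662) or 3 (adjusted p = 0.0520). T cell identity genes were also lower as a set (adjusted p = 0.0295; adjusted p = 0.551 with an estimated correlation), a call lost without the same replicates (adjusted p = 0.103 and 0.0619). 3 of its 17 members fell, and 4 did adjusted over the list alone. The 3 were the signalling adaptor gene LCP2 (2.56-fold) and the T cell receptor genes TRBC1 (1.46-fold) and TRBC2 (1.34-fold). The TRBC1 call was lost without wild-type replicate 3 or 4 or FOXP3-null replicate 1, 2 or 4 (adjusted p from 0.0654 to 0.0833), and the TRBC2 call without any 1 of the 8 libraries (adjusted p from 0.0566 to 0.140).

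**Figure D2:**
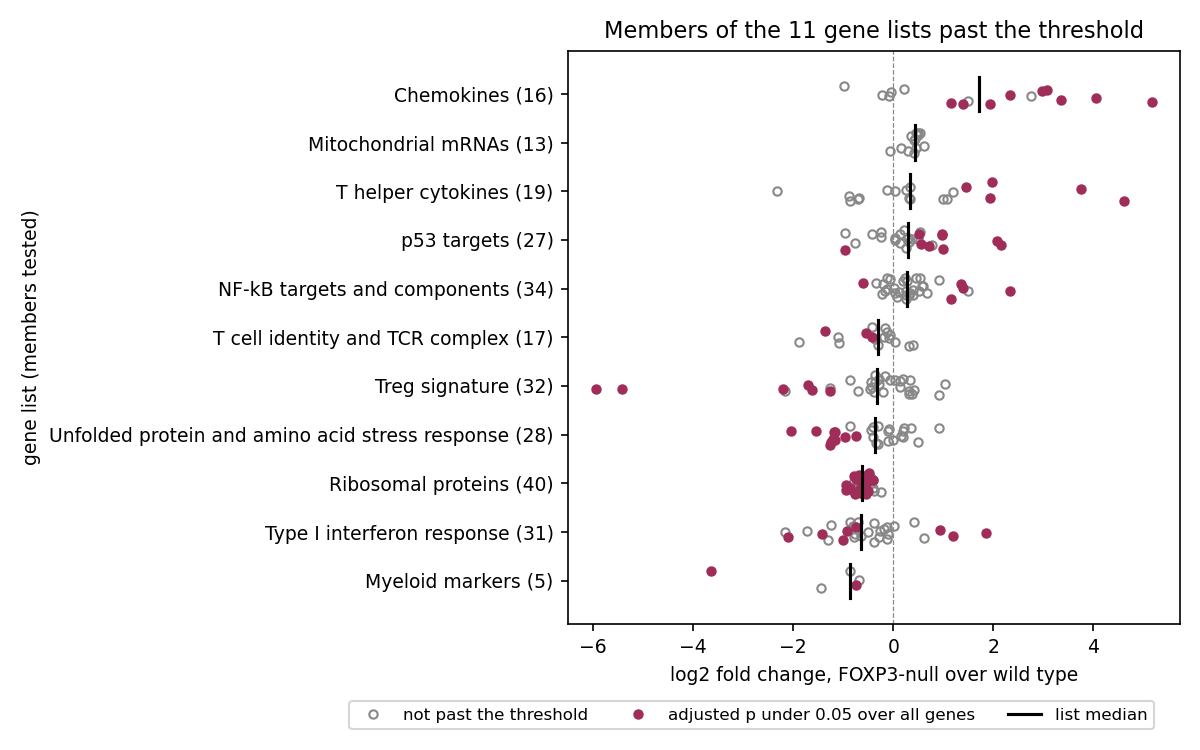
Log2 fold change (FOXP3-null over wild type) of each tested member of the 11 gene lists past the camera threshold, with filled points for members past the threshold over all genes and a line at the list median. Chemokines had the highest median, 1.71, and the median of the ribosomal proteins was -0.62.

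Markers of other cell types were sparse. Of 18 myeloid markers 5 were tested and 2 fell, CSF1R (12.6-fold, holding a ribosomal protein pseudogene on its other strand) and CEBPA (1.67-fold), with 3 adjusted over the list alone. That list was lower in camera (adjusted p = 0.00239; adjusted p = 0.230 with an estimated correlation), and the call was lost without wild-type replicate 2 (adjusted p = 0.0814). CD22 was the 1 of 10 tested B cell markers to pass and fell 7.91-fold, with 1 rising and 1 falling adjusted over the list alone (list adjusted p = 0.362). 1 of 3 natural killer cell markers fell, NCR1, by 1.51-fold, with 2 adjusted over the list alone (list adjusted p = 0.147), and its call was lost without any 1 of the 8 libraries (adjusted p from 0.0528 to 0.121). Of 7 epithelial and fibroblast markers THY1 rose 1.85-fold, also 1 adjusted over the list alone (list adjusted p = 0.298). Of 4 erythroid and megakaryocyte markers 0 passed in edgeR, DESeq2 or limma-voom, also 0 adjusted over the list alone, and 2 had an unadjusted p under 0.05 in edgeR (list adjusted p = 0.132).

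The other lists did not move as sets in camera (adjusted p from 0.121 to 0.909), although some of their members changed. Among chemokine and homing receptors 3 of 25 rose and 5 fell (5 and 5 adjusted over the list alone), ITGB7 falling 5.41-fold and CCR9 5.00-fold, both overlapping expressed genes of the other strand, ZNF740 and LZTFL1, of which LZTFL1 also fell (adjusted p = 0.00160). In the TNF and TNF receptor superfamily 4 of 23 rose and 2 fell (5 and 2 adjusted over the list alone): TNFSF4, the ligand OX40L, rose 2.04-fold to 544 ± 85.7 CPM and TNFSF14 fell 4.38-fold. Among immune checkpoints 4 of 17 rose and 1 fell (4 and 2 adjusted over the list alone), with CD226 rising 1.91-fold and CD244 falling 25.9-fold. Among T helper lineage regulators 5 of 37 rose and 1 fell (5 and 2 adjusted over the list alone), the homeobox gene HLX rising 5.21-fold. Among cytotoxic effector genes 2 of 11 rose and 2 fell (2 and 4 adjusted over the list alone), NCR3 falling 8.997-fold. Of the genes associated with adult T cell leukaemia 1 of 25 rose and 1 fell, as also adjusted over the list alone, PTHLH rising 4.75-fold. Of apoptosis regulators 0 of 27 rose and 2 fell, as also adjusted over the list alone, the caspase gene CASP6 falling 4.36-fold from 97.46 ± 8.50 to 22.4 ± 1.91 CPM (SD, n = 4 each). CASP6 shares 98 bases with MCUB on the other strand, which also fell (adjusted p = 0.000946).

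Among immediate early and AP-1 genes 3 of 30 rose (5 rising and 1 falling adjusted over the list alone), IER3 by 1.79-fold. Of IL-2 and STAT5 targets 1 of 29 rose and 1 fell (2 and 3 adjusted over the list alone), CCND3 rising 1.63-fold and PIM1 falling 1.92-fold, the CCND3 call being lost without FOXP3-null replicate 2 (adjusted p = 0.0514). In glycolysis the glucose transporter gene SLC2A1 was the 1 of 27 to rise, 2.31-fold from 91.3 ± 4.13 to 211 ± 25.7 CPM (SD, n = 4 each), also 1 adjusted over the list alone. 1 of 34 oxidative phosphorylation genes rose, SDHA (1.60-fold), and 0 did adjusted over the list alone; the SDHA call was lost without wild-type replicate 3 or 4 or FOXP3-null replicate 1, 2 or 4 (adjusted p from 0.0859 to 0.129). 1 of 27 cholesterol synthesis genes rose, SC5D (1.53-fold, 1 adjusted over the list alone), a call lost without wild-type replicate 3 or FOXP3-null replicate 3 or 4 (adjusted p from 0.0595 to 0.0825). 1 of 25 antigen presentation genes fell, CTSS (2.24-fold, 1 adjusted over the list alone), a call lost without wild-type replicate 3 or FOXP3-null replicate 1, 2 or 4 (adjusted p from 0.0530 to 0.0776). 0 of 40 cell cycle genes passed in the edgeR test, also 0 adjusted over the list alone, while 6 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. Leaving out 1 library brought 4 of these lists past the camera threshold: cell cycle without FOXP3-null replicate 3 (adjusted p = 0.0292), immediate early genes without FOXP3-null replicate 2 (adjusted p = 0.0109), and glycolysis and oxidative phosphorylation without wild-type replicate 4 (adjusted p = 0.0484 and 0.0385). The antigen presentation list passed camera, as lower, with the replicate block (adjusted p = 0.0454) and without the filter on low counts (adjusted p = 0.0283), against 0.121 in the main fit.

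In all, 11 of the 30 lists passed camera with the preset correlation, 5 higher and 6 lower, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05; fry called 9. 12 of the 35 ways of splitting the 8 libraries into 4 and 4, the real one included, gave at least 11 lists.

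17 genes were detected in one line only, 10 in the wild type and 7 in the FOXP3-null line. 15 of them passed the edgeR threshold. The wild-type genes included BEX2 (63 to 436 counts per library) and TEX15 (42 to 51 counts). The FOXP3-null genes included CTSE, HCST and TEKT4. These names were chosen after their values were seen. In a rule that needs every library, leaving one out can only admit more genes, and the count became 36, 30, 30, 26, 27 and 29 without wild-type replicates 1, 2 and 3 and FOXP3-null replicates 1, 3 and 4.

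Along chromosome 10 the change was regional. From 116881477 (the start of SHTN1, GRCh38) to the end of the last gene tested at 133422520, the median log2 fold change of 68 genes above 1 CPM was -0.86 (interquartile range -1.12 to -0.75), and 66 of them were negative. On the rest of the chromosome the median of 468 such genes was 0.06 (interquartile range -0.21 to 0.31). 48 of the distal genes were called lower and 2 higher. The distal median lay between -0.96 and -0.82 in each of the 4 FOXP3-null libraries, and between -0.07 and 0.09 in each wild-type library measured against the other 3. The border was placed after the values were seen, at the point that best parted the chromosome.

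**Figure D3:**
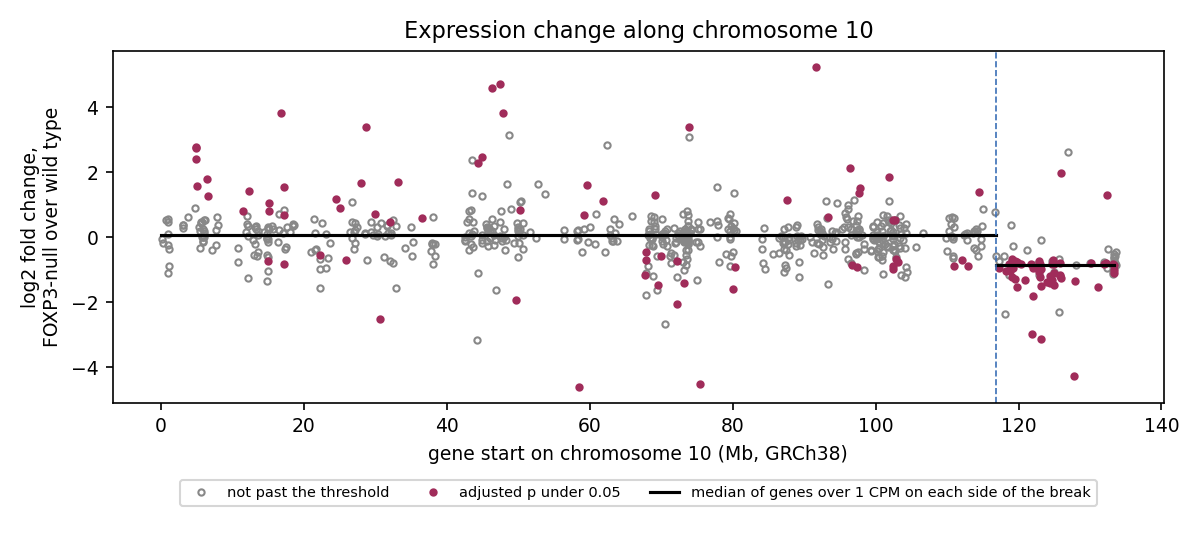
Log2 fold change (FOXP3-null over wild type) of each tested gene on chromosome 10 against its start in Mb (GRCh38), with filled points for genes past the threshold, lines at the medians of genes above 1 CPM and a dashed line at the border. The median stood at 0.06 before the border and at -0.86 after it.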

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

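Values far from the other 3 of their line were searched for in 254 sets of 4 libraries, namely the CPM of each named gene and 4 library measures in each line, by the gap to the nearest library divided by the range. The search picked 14 sets, which is 5.51%. Chance alone picks about 1 in 20, or 12.7 sets here.

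Among FOXP3-null libraries, replicate 3 was highest for IFNG (1.14 CPM, next 0.167), FN1 (11.8 CPM, next 2.89) and IL1A (116 CPM, next 85.4). Replicate 4 was highest for ITGAM (0.731 CPM, next 0.3002), CCR9 (1.59 CPM, next 0.931) and LCP2 (58.2 CPM, next 50.02), and lowest for TRBC1 (12.6 CPM, next 15.6). Replicate 1 was highest for CCL1 (13.2 CPM, next 6.85) and PRKCB (67.7 CPM, next 50.5), and its 10 most abundant genes held 8.02% of counts against 7.10% in the next library.

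Among wild-type libraries, replicate 2 was highest for IL6 (1.62 CPM, next 0.957) and ACTA2 (83.5 CPM, next 67.3). Replicate 4 was highest for IL9 (15.6 CPM, next 4.75), and replicate 1 for FN1 (6.08 CPM, next 1.48). The lines did not overlap for IL9, IL6, IL1A, CCL1, CCR9, LCP2 and TRBC1.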

How the results depend on the processing

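The length and GC correction was chosen after seeing the data; the other alternatives were planned. FOXP3 passed the threshold in all 22 alternatives, with log2 fold changes from -4.51 to -3.67 and adjusted p from 1.25e-11 to 0.00865. The 1821 changed genes became 2948 with DESeq2 (its adjusted p was missing for 11277 genes with a count), 802 with limma on log2(TPM + 1) without a filter and 680 at an adjusted p of 0.01. The count ranged from 977 to 1956 when single libraries were left out. The 1016 genes above 2-fold became 595 with limma on log2(TPM + 1), 452 without its filter, 549 at an adjusted p of 0.01 and 239 with glmTreat, which tests against a 2-fold change and is stricter by construction. Leaving out single libraries gave 735 to 1170. The cause of the difference between tools was not tested. The share of higher calls was 48.8%, and 65.3% to 67.0% in the 3 TPM settings. With limma on log2(TPM + 1) the median of all genes lay at 0.13 on the log2 scale.

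The 11 gene lists became 0 with an estimated correlation, and 8 to 13 when single libraries were left out. In fry the NF-kB, type I interferon, T cell identity and mitochondrial lists did not pass (adjusted p of 0.0683, 0.129, 0.0811 and 0.242), and the natural killer cell and erythroid lists did (0.0103 and 0.0209). The 17 genes detected in one line only became 4 at 20 counts against 0 and 50 at 5 counts against 2, and 19 to 36 when single libraries were left out. The number of shifted chromosomes, 6, became 4 to 7, and which ones passed differed: chromosome 15 was lost in most settings and chromosome 8 in 1. Chromosome 20 was gained with protein-coding genes only (adjusted p = 0.0451). Chromosome 12 was gained without wild-type replicate 3 (adjusted p = 0.0224) or FOXP3-null replicate 3 (adjusted p = 0.0439), and chromosome 21 without FOXP3-null replicate 3 (adjusted p = 0.0272).

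Replicate numbers are shared by the lines, but the labels do not say that a number marks a shared day. The experiment was carried out 4 times, so same-numbered libraries may share one. Deviations of same-numbered libraries correlated by -0.04 to 0.22, above 0.1 in 2 of 4 pairs, and 4 of 8 libraries correlated best with their own number. These values neither establish nor exclude pairs. The fit without pairs was kept as the main one because it was planned and the labels state no pairing. With the replicate block 2324 genes were called, 1685 of them among the 1821 and in the same direction.

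Of 122 named genes 87 were called, and 71 of these kept the call whichever single library was left out. Among those in the text, ABCB1, CTSS, CYLD, NCR1, TRBC1 and TRBC2 lost the call in all 3 TPM settings (adjusted p from 0.0556 to 0.288), and PPP1R3F, SAMD9, SC5D and SDHA in the TPM setting without a filter (0.0652 to 0.113). CYLD, NCR1 and TRBC2 also lost it with library size only (0.0507, 0.0633 and 0.0708), NCR1 and TRBC2 without a filter on low counts (0.0609 and 0.085) and NCR1 with the replicate block (0.0671). IFNG changed sign with the replicate block (-0.18), without wild-type replicate 1 (-0.14) and without FOXP3-null replicate 3 (-1.66), and FN1 without FOXP3-null replicate 3 (-0.0817), neither being called. Leaving out single libraries gave log2 fold changes of -1.66 to 1.43 for IFNG and -0.0817 to 2.08 for FN1. Depth limits genes with few counts, such as IL2, which did not pass the filter on low counts.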

Other observations

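Tests of the residual FOXP3 transcripts, of chromosome 10 and of gene families, and the length and GC correction, were chosen after the results were seen; the other tests were planned.

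Families of genes sharing a symbol stem, 163 in all, were tested with camera at the preset correlation. A stem was the symbol up to its first digit, so RPL and RPS can also hold genes that are not ribosomal proteins. The stems RPL (28 of 51 genes lower) and RPS (17 of 42 lower and 1 higher) fell, and the chemokine stem CCL rose (6 of 10 higher). 2 other stems passed: ANXA, mostly annexins, which bind membranes in the presence of calcium, with 3 of 10 genes higher and 2 lower (adjusted p = 0.00270), and SOX, a family of developmental transcription factors, with 2 of 12 higher (adjusted p = 0.00988). The ANXA stem holds ANXA8 and ANXA8L1, near-identical copies whose separate counts are uncertain (log2 fold changes 4.72 and 4.60). Its test was not repeated without them, so how far the call depends on them is not known. With an estimated correlation no family passed (adjusted p = 0.992). By chromosome, median log2 fold changes were shifted on chromosome 11 (0.15), 16 (0.09), 2 (-0.09), 8 (-0.08), 15 (-0.05) and the mitochondrial genome (0.37). The chromosome 15 shift was lost with mean CPM over 10, with protein-coding genes only, with the replicate block, without wild-type replicate 2, 3 or 4 and without FOXP3-null replicate 2 or 3 (adjusted p from 0.0501 to 0.332), and the chromosome 8 shift with mean CPM over 10 (adjusted p = 0.0760). The mitochondrial genome was not tested with protein-coding genes only. 10 of the 35 splits of the libraries shifted at least 6 chromosomes, and the highest other split shifted 13, so chance cannot be excluded for this count.

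A candidate explanation for the distal part of chromosome 10 is the loss of 1 of 2 copies in the FOXP3-null line. Such a loss predicts a median near -1 that runs to the chromosome end in every FOXP3-null library. The median was -0.86, 97.1% of the 68 genes were negative, and the 4 libraries lay between -0.96 and -0.82. Copy number was not measured, and a doubling of the copies in the wild-type culture would give the same ratio. FANK1, in the regulatory T cell list, lies in this part, as do MKI67 (log2 fold change -0.85, adjusted p = 0.133) and BNIP3 (-0.75, adjusted p = 0.220). The best single border on any other autosome or on X removed at most 5.97% of the deviation of the fold changes, against 17.3% on chromosome 10.

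For the 1821 changed genes, 1 of the 35 splits, the real one, gave as many, and the highest other split gave 2. A share of 1 in 35 is the smallest that these splits allow. Every other split mixes the lines, so the difference between the lines widens the spread within each side and lowers the calls. The splits therefore do not decide whether chance gave this count. The same held for the 1016 genes above 2-fold (1 of 35, highest other 2) and for the 17 genes detected in one line only (1 of 35, highest other 3). For the 11 gene lists 12 of 35 splits gave as many and the highest other split gave 14, so chance cannot be excluded. The split with 14 held 2 libraries of each line on each side. Splits with 3 libraries of 1 line on a side keep part of the line difference, so 12 of 35 is not a chance rate. Copy-number differences over broad regions were tested by windows of 10 Mb. Of these, 24 of 285 had a shifted median and held 14.1% of the changed genes, against 9.92% of all tested genes. This argues against such broad differences as the main source, although the distal part of chromosome 10 alone held 5.15% of the lower genes. Windows with fewer than 20 genes and copy-number changes of smaller regions were not tested. On chromosome 11 the best single border left a median of 0.23 for the 532 genes past it, against -0.01 for the 218 before. Named genes in shifted windows include SC5D and THY1 on chromosome 11, SDHA on 5, MX1 and MX2 on 21 and TNFAIP2 on 14. In this order, their log2 fold changes were 0.61, 0.89, 0.67, 1.18, 1.86 and 1.35. The shifts of their windows were 0.20, 0.26, 0.32, 0.19, 0.19 and 0.24. IL2RA, which was not called, had a log2 fold change of 0.19 in a window on chromosome 10 shifted by 0.29. CTSW, NCAM1 and EPCAM moved against the shift of their window. What stays open is any other difference between the single FOXP3-null line and its parent: with 1 knockout line, effects of FOXP3 and of the selection of that line cannot be told apart.

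The residual FOXP3 transcripts might come from wild-type cells or reads mixed into the FOXP3-null libraries. Such a mixture would hold every gene of the wild-type cells to at least its own share. The comparison used 16 other protein-coding genes past the threshold, with a log2 fold change below -4 and a wild-type mean of at least 5 CPM. In all 4 FOXP3-null libraries their median, 1.71%, 1.39%, 2.28% and 1.95% of their wild-type level, lay below that of FOXP3, 2.11%, 3.36%, 12.5% and 7.68%. The limit of -4 lies just below the value of FOXP3, -3.96, so this order of the medians was largely set by the choice. Among the 16 are CT45A3, CT45A5, CT45A6 and CT45A7, which are near-identical copies. All 16 genes were picked for being low, so they bound a mixed-in share and say nothing of typical genes. A stricter form of the test was run first, with the 90th percentile in place of the median; it held in 3 of 4 libraries and not in replicate 1, where 10 of the 16 genes lay below FOXP3, and the median was adopted after that was seen. CREB5 held 0.489%, 0.137%, 0.115% and 0.253% of its wild-type level, below the percent of FOXP3 in all 4 libraries. If mixed-in cells held CREB5 near its wild-type mean, this argues against a mixture as the whole source of the residual FOXP3. That reading rests on a single gene whose level varied between wild-type libraries. A mixed-in share up to the percent of CREB5 and a transcript that persists after editing both stay open, since the edited sequence was not examined.

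The lower ribosomal protein mRNAs might reflect a length or GC bias, since they are short. After a correction of both in each library the median was -0.60, with 24 of 40 called lower. In the same range of length, 2812 other well expressed protein-coding genes had a median of 0.07. Length and GC were medians over all annotated transcripts of a gene, which can differ from those of the mRNA expressed. The values argue against a bias along these measures as the whole cause. They do not decide on a bias against mRNAs that are short as expressed. A planned comparison with 3 other scalings of the libraries decides nothing: a scaling shifts all genes alike, so the median relative to all genes had to stay at -0.62. Reads shared with pseudogenes were not tested, and the list's call was lost with an estimated correlation (adjusted p = 0.367). A biological difference in the FOXP3-null line is a hypothesis that these data do not decide. Whether such a difference would come from FOXP3 could be examined only with a second edited line.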
